A study of Mus musculus with 6 samples.

How the data were processed

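Gene expression was measured by RNA-seq in 6 whole-liver samples of C57BL/6 mice, an inbred laboratory strain. Per the labels, 3 samples were wild type and 3 carried a knockout of Cdkl3, a gene of the cyclin-dependent kinase-like family. All were labelled as from male mice on a chow diet and 10 months old. Per the labels' protocols, livers were frozen, RNA was extracted with Trizol and libraries were made from total RNA by Illumina protocols. Per the submitters' processing notes, HISAT2 and the GRCm39 mouse genome were used. The version of the aligner, the counting tool and the gene annotation are not given in the sources used here. Each deposited table holds 1 FPKM value per row (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers, with an identifier and a gene symbol. In 1 of the 6 tables, the library labelled knockout replicate 3, the sample code in the header differs from the title of the sample, and the label of the sample was used.

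The identifier and the symbol of a row named the same gene in 0 of 24927 rows, although 24514 identifiers were in the mouse annotation, so it was tested which of them fits the values. If whole reads were counted, FPKM multiplied by the exon length of the right gene is a whole multiple of a fixed step in each library. With exon lengths from GENCODE M21 (GRCm38) taken by symbol, 98.91% of 43312 low values outside the chromosome 1 rows were whole to within 0.15 read, up to 40 reads. By identifier the share was 29.98%, with 30% expected by chance. In the 1787 rows of the chromosome 1 block the share by symbol was 35.74%, and on the other chromosomes it ran from 97.81% to 99.79%. Symbols were therefore used, identifiers were not, and the chromosome 1 block was left out of tests and of named genes, with 127 further rows without a symbol. M21 served only for exon length, GC content and the location of Cdkl3, by symbol, and 23755 symbols matched it once. The steps also gave the depth, from about 20460000 to 48610000 reads or read pairs counted on genes per library, at which 1 read on a 1 kb transcript is worth 0.0206 to 0.0489 FPKM. On simulated libraries of known depth the recovered depth was off by 0%.

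FPKM values are not counts, so the branch of the design for normalized values was used. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (mean-variance trend and robust moderation), with the labelled genotype as the only term, over 5673 genes with at least 1 FPKM in at least 3 libraries. The Benjamini-Hochberg adjusted p had to be under 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and all group values are mean ± SD (n = 3). Ratios of group means are on the FPKM scale. Data were simulated for the comparison of knockout and wild type, from the real means and spreads of 5673 genes. The fit recovered 63% of 100 genes changed by 1 on the log2 scale and 90% of 100 genes changed by 2, and it called 7 unchanged genes. The simulated genes varied independently, few of them changed and no library had a trend on GC content. These rates therefore need not hold for the real libraries. Labels give each library as a separate sample and do not say in words that each came from its own mouse, so the p-values measure the spread between these libraries.

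Gene lists numbering 42, for liver pathways, stress, growth and the cell types a liver piece can hold, the rule for named genes and the other settings tried were written before the data were examined. The rule named Cdkl3 and its family. It also named the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted gene models. From each list it allowed up to 4 members with the smallest adjusted p, or up to 2 members as values where none passed. Xist and 4 Y-linked genes were added after their values were seen. Some genes that the rule names are not reported here. Lists with at least 3 tested members (33 of 42) were compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted over the 33 lists, and again with the correlation estimated from the residuals. Alternatives were another pseudocount, no filter and a stricter filter, other thresholds, a fit without robust moderation, a replicate block, leaving out each library, and fry for the lists. Chosen after seeing the data were median centring, quantile normalization, removal of each library's loess trend on GC content, or on GC content and exon length (possible for 5539 of the tested genes, or 97.64%), and adding the chromosome 1 rows. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.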

Results

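The data are 6 mouse liver transcriptomes in 2 groups of 3, the libraries labelled wild type and the libraries labelled Cdkl3 knockout. The series asks what loss of Cdkl3 does to gene expression in the liver of mice on a chow diet. The libraries labelled wild type held about 36040000, 48610000 and 20460000 counted reads, and those labelled knockout 24530000, 39550000 and 26720000. Mitochondrial transcripts made up 73.67%, 73.88% and 70.47% of all FPKM in wild type replicates 1 to 3, and less in each library labelled knockout, with 69.48%, 70.11% and 63.17%. Rows with at least 1 FPKM numbered 5038 to 5437 in the libraries labelled wild type and 6016 to 6388 in those labelled knockout.

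Cdkl3 was listed at a low FPKM and did not differ detectably between the libraries labelled knockout and those labelled wild type. It measured 0.124 ± 0.039 FPKM (SD, n = 3) in the libraries labelled wild type and 0.139 ± 0.060 FPKM (SD, n = 3) in those labelled knockout. The values correspond to 32, 23 and 13 reads in wild type replicates 1 to 3 and to 10, 31 and 28 reads in knockout replicates 1 to 3. The pooled read rate in the libraries labelled knockout was 1.17 times that in the libraries labelled wild type, with a 95% exact binomial interval from 0.828 to 1.67 that covers counting error only. A two-sided exact permutation test of the FPKM values gave p = 0.8, where 3 against 3 libraries cannot go below 0.1. The log2 difference was 0.02 (SE 0.06, 95% interval -0.13 to 0.17, limma adjusted p = 0.84 in a fit of 20529 genes without a filter). On the log2(FPKM + 1) scale even a complete loss of a gene at 0.124 FPKM is a small negative difference. This last interval therefore does not exclude a large partial loss. Genes used by most cells were listed lower still in the libraries labelled wild type. Gapdh had a mean of 0.0079 FPKM and Rplp0 of 0.0752 FPKM, both chosen after their values were seen. A low FPKM in these tables thus does not by itself show low expression. The Gapdh and Rplp0 transcripts have 52.6% and 52.9% GC, against 44.5% for Cdkl3, so they do not show poor recovery of Cdkl3. The gene lies on the plus strand of chromosome 11 at 52004221 to 52089784 (GRCm38, GENCODE M21), and a value per gene cannot show the loss of part of its exons. Among other members of its family, Cdkl2 measured 2.27 ± 0.541 and 1.98 ± 0.269 FPKM in the libraries labelled wild type and knockout. Cdkl1 measured 0.0384 ± 0.0502 and 0.160 ± 0.142 FPKM and Cdkl4 0.195 ± 0.0701 and 0.0382 ± 0.0318 FPKM. The adjusted p was 0.56 for Cdkl2 and, without the filter, 0.3 for Cdkl1 and 0.058 for Cdkl4.

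Sex-linked genes separated the groups, although the labels call all mice male. Xist, the noncoding RNA that coats the inactive X chromosome, measured 253 ± 53.9 FPKM in the libraries labelled wild type and 0.0212 ± 0.00774 FPKM in those labelled knockout. The Y-linked genes Ddx3y and Eif2s3y measured 0.120 ± 0.0757 and 0.565 ± 0.281 FPKM in the libraries labelled wild type, against 45 ± 6.35 and 47.6 ± 3.94 FPKM in those labelled knockout. Uty measured 0.0261 ± 0.0214 against 7.62 ± 1.02 FPKM, and Kdm5d was listed at 0 in each library labelled wild type and measured 2.08 ± 0.091 FPKM in those labelled knockout. The pattern held in 6 of 6 libraries, and Xist and the Y-linked genes were chosen after their values were seen. Sex as shown by these genes and labelled genotype vary together, so each difference below is between libraries that differ in both.

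**Figure D1:**
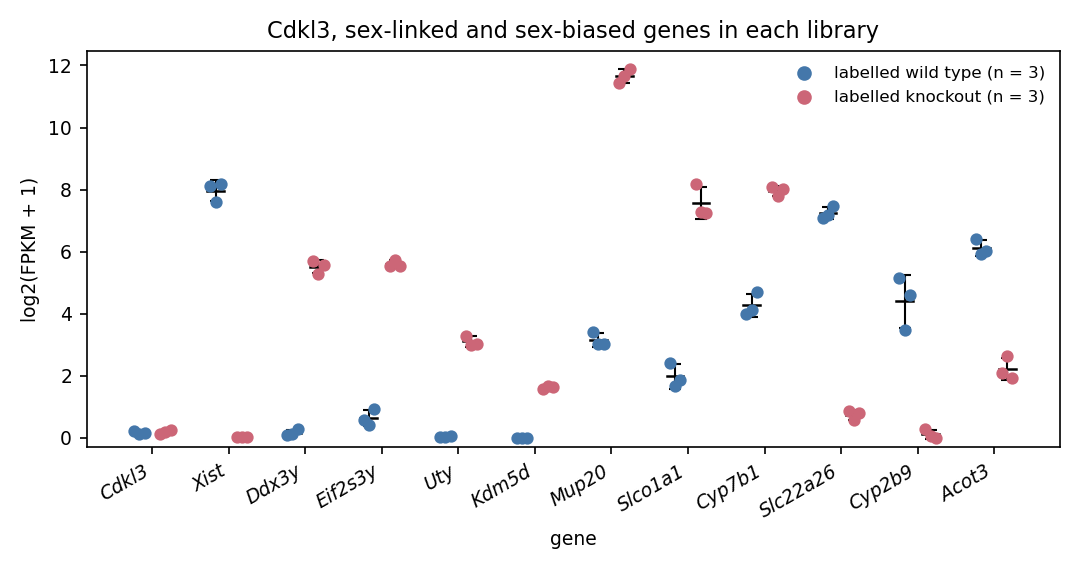
Expression of Cdkl3, Xist, Y-linked genes and sex-biased liver genes, as log2(FPKM + 1) on the vertical axis, by gene. Points are libraries, 3 labelled wild type (blue) and 3 labelled knockout (red), with the mean and SD as black lines. Cdkl3 overlaps between the groups, and Xist at 253 FPKM in the libraries labelled wild type lies at 0.0212 FPKM in those labelled knockout.

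Of 5673 genes tested, 1911 were higher and 1157 lower in the libraries labelled knockout. The largest rises were in major urinary protein genes, which encode pheromone carriers secreted by the liver, and in serine protease inhibitors. Mup20 rose from 7.95 ± 1.48 to 3257 ± 492 FPKM (adjusted p = 2.6e-07), Mup14 from 1.26 ± 0.601 to 806 ± 338 FPKM and Mup18 from 1.57 ± 1.15 to 158 ± 43.8 FPKM. Serpina1e, of the alpha-1 antitrypsin family, rose from 0.0815 ± 0.0272 to 667 ± 173 FPKM (adjusted p = 2.6e-07), and Serpina3k from 6.59 ± 2.64 to 602 ± 208 FPKM. Mup7, Mup11, Mup12, Mup13 and Mup17 completed the 10 largest rises, with log2 differences of 7.23 to 10.96. The largest falls were in Xist, in the sulfotransferases Sult3a1 and Sult2a2, in the organic anion transporters Slc22a26 and Slc22a27, and in the cytochromes P450 Cyp2b9, Cyp2a22 and Cyp4a14. Slc22a26 fell from 151 ± 21.0 to 0.673 ± 0.17 FPKM, Cyp4a14, a fatty acid hydroxylase, from 5444 ± 830 to 469 ± 329 FPKM, and Sult3a1 from 344 ± 242 to 0.0527 ± 0.0464 FPKM. The thioesterase Acot3 fell from 69.1 ± 12.9 to 3.75 ± 1.26 FPKM and the leptin receptor Lepr from 30.8 ± 10.6 to 1.72 ± 0.794 FPKM. These Mup, Serpina, Sult, Slc22a and Cyp genes have near-identical copies among which reads can be split, so the values of single members are uncertain.

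The groups did not overlap in 63.86% of the tested genes, where chance gives 10%. The first principal component held 80.39% of the variance and parted the groups, with Pearson's r across genes of 0.9496 to 0.9774 within groups and 0.7396 to 0.8531 between them. The balance of rises and falls depended on scaling and on the filter, and FPKM outside the mitochondrial transcripts took a larger share in each library labelled knockout. More rows reached 1 FPKM in the libraries labelled knockout, and a gene could pass the filter through that group alone. This bears on the counts of each list below. At 10 FPKM or more in 3 libraries, 468 genes were higher and 559 lower. The median log2 difference over all tested genes was 0.12, median centring lowered each difference by 0.28, and the counts were then 1443 higher and 1891 lower, or 1427 and 1761 after quantile normalization. Without knockout replicate 1, 2 or 3 the higher genes numbered 1241, 966 and 1058, and without wild type replicate 3 the lower genes numbered 727. The filter still asked for 3 libraries, so genes at 1 FPKM or more only in the group that lost a library were not tested. Without knockout replicate 1, 2 or 3 the tested genes numbered 4993, 4976 and 4938, with a median log2 difference of 0.015, 0.0046 and -0.020. List tests without a knockout replicate, below, compare with these fewer genes. Mup7 was not called without knockout replicate 2, Mup17 without wild type replicate 3 or knockout replicate 1, and Mup13 without wild type replicate 3 or any of the 3 knockout replicates. Knockout replicate 1 also held 5264 FPKM of Kap, a kidney transcript, against at most 5.72 FPKM in any other library.

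The difference between groups also went with the base composition of transcripts. Among transcripts under 40% GC, 11.76% were higher and 39.86% lower in the libraries labelled knockout, and among those of 50 to 55% GC, 55.74% were higher and 11.48% lower. Across 5539 genes, which are not independent replicates, Spearman's rho of the log2 difference with GC content was 0.357, and with exon length -0.168. Libraries of the same group differed in these trends too. For the deviation of a library from its group mean, rho with GC content ran from -0.264 (wild type replicate 3) to 0.214 (knockout replicate 2). With exon length it ran from -0.296 (knockout replicate 2) to 0.215 (knockout replicate 1). After removal of each library's trend on GC content and length, 1488 genes were higher and 1369 lower. List counts after this removal are given below as trend-corrected counts.

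**Figure D2:**
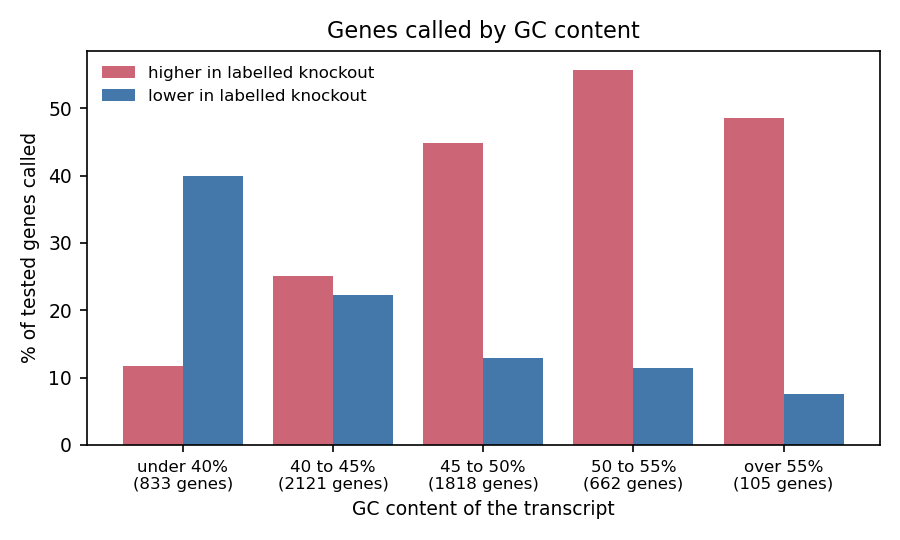
Share of tested genes called higher (red) or lower (blue) in the libraries labelled knockout, in percent, by GC content of the transcript. The share called higher is 11.76% under 40% GC and 55.74% at 50 to 55% GC.

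Of the 33 lists tested against all other genes, 8 passed the threshold with the preset correlation and 0 with an estimated correlation. Counts of rises and falls below are out of the tested members, and the other members of a list were under the filter or had no usable row. Counts adjusted over the list alone were the same as over all genes in 31 of the 39 lists with a tested member, and the 8 others are given with their list. The male-biased liver genes rose together, 13 of 13 tested (camera adjusted p = 1.1e-07). Cyp4a12b, a fatty acid hydroxylase, rose from 0.00573 ± 0.00992 to 22.4 ± 5.28 FPKM, and the transporter Slco1a1 from 3.03 ± 1.15 to 198 ± 78.4 FPKM. Of 13 tested female-biased genes 10 fell and none rose (adjusted p = 2.9e-07), among them Slc22a26, Acot3 and Sult3a1, and Cyp2b13, which went from 6.60 ± 1.57 FPKM to a listed 0. With an estimated correlation the adjusted p was 0.17 for the male-biased and 0.14 for the female-biased list. Some of their members are also on lists given below. Slco1a1 is on the bile acid list, Cyp2b13 on the xenobiotic metabolism list and Acot3 on the list of PPAR alpha targets. Results of those lists are therefore not separate from those of the sex-biased genes. After the trend correction 13 male-biased genes were higher and 11 female-biased genes lower.

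Transcripts of secreted plasma proteins were higher in the libraries labelled knockout. In the hepatocyte secretory list 10 of 12 tested members rose and none fell (camera adjusted p = 0.0040). Serpina1a rose from 0.509 ± 0.361 to 24.1 ± 12.0 FPKM, transthyretin (Ttr) from 24.3 ± 8.96 to 119 ± 31.5 FPKM and prothrombin (F2) from 0.452 ± 0.186 to 4.58 ± 1.76 FPKM. Of 11 acute phase protein genes 8 rose and none fell (adjusted p = 0.0079), with orosomucoid Orm1 at 2.15 ± 0.899 and 184 ± 79.6 FPKM, complement C3 at 0.312 ± 0.148 and 12.5 ± 6.25 FPKM and the fibrinogen chain Fga at 7.03 ± 4.03 and 123 ± 43.6 FPKM. In the unfolded protein and integrated stress response list 9 of 12 rose and none fell (adjusted p = 0.024). There the transcription factor Xbp1 rose from 6.57 ± 1.27 to 22.4 ± 6.60 FPKM, and the chaperones Calr from 1.05 ± 0.635 to 16.7 ± 9.93 FPKM and Pdia4 from 0.431 ± 0.0801 to 7.54 ± 4.37 FPKM. Nuclear genes of oxidative phosphorylation rose in 12 of 17 cases and fell in none (adjusted p = 0.0036), such as Ndufv2 from 4.82 ± 1.69 to 41.9 ± 5.95 FPKM and Uqcrc2 from 0.682 ± 0.391 to 9.55 ± 2.42 FPKM. Of the genes named here, Serpina1a, F2, C3 and Pdia4 were under 1 FPKM in each library labelled wild type. They passed the filter only through the libraries labelled knockout, so they could hardly have been counted as falls. With an estimated correlation the adjusted p was 0.78 for each of these 4 lists. With the preset correlation the camera adjusted p of the stress response list rose from 0.024 to 0.087 without wild type replicate 1. The trend-corrected counts were 10 higher and 0 lower of the secretory, 8 and 1 of the acute phase, 8 and 0 of the stress response and 9 and 1 of the oxidative phosphorylation list. With that correction the median log2 difference fell from 1.89 to 1.24, 1.96 to 1.19, 1.45 to 0.90 and 1.39 to 0.97 in this order, and the adjusted p was 0.68 for each list with an estimated correlation. Knockout replicate 1, which held the kidney transcripts, had the lowest mean log2(FPKM + 1) of the libraries labelled knockout in each of these lists. Over the 23 listed stress response genes it was 2.77, against 3.75 and 3.52 in knockout replicates 2 and 3 and 2.12 to 2.29 in the libraries labelled wild type.

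Heat shock genes rose in 4 of 8 cases and fell in none (camera adjusted p = 0.081, and 0.035 after median centring). With an estimated correlation the adjusted p was 0.78, and 0.75 after median centring. The mean log2(FPKM + 1) over the 14 listed genes was 2.00 in knockout replicate 1, against 2.83 and 2.75 in knockout replicates 2 and 3. Without knockout replicate 1 the camera adjusted p with the preset correlation was 0.0093, over the fewer genes then tested. Hspa8 measured 0.814 ± 0.316 and 32.6 ± 23.8 FPKM and Hsp90ab1 0.493 ± 0.240 and 17.6 ± 8.70 FPKM in the libraries labelled wild type and knockout. Of 8 tested cytosolic ribosomal protein genes 5 rose and none fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.25), and Rpl5 went from 4.67 ± 1.26 to 39.2 ± 10.4 FPKM. The trend-corrected counts were 5 and 0 for heat shock and 4 and 2 for ribosomal proteins. The 13 mitochondrially encoded mRNAs went both ways, with 3 higher and 4 lower (adjusted p = 0.50). The balance depended on scaling, with 1 higher and 6 lower after median centring and trend-corrected counts of 3 and 2. Here mt-Nd4l rose from 102 ± 30.9 to 418 ± 181 FPKM and mt-Nd3 fell from 1054 ± 442 to 324 ± 84.8 FPKM, and the call of mt-Nd3 was lost after correction for GC content alone.

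Several lipid synthesis genes rose in the libraries labelled knockout. Of 11 tested genes of cholesterol synthesis and uptake 6 rose and none fell, or 7 and 0 adjusted over the list alone. The sterol demethylase Cyp51 rose from 6.56 ± 3.73 to 65.4 ± 42.2 FPKM and Nsdhl from 3.19 ± 1.35 to 17.5 ± 8.60 FPKM. Of 10 tested fatty acid and triglyceride synthesis genes, from 22 listed, 6 rose and 1 fell. Fasn, Acaca, Srebf1 and Dgat1 were among those under the filter. The desaturases Scd1 and Fads1 rose from 187 ± 61.9 to 1321 ± 629 FPKM and from 0.524 ± 0.374 to 15.5 ± 6.37 FPKM, the acyltransferase Gpam rose from 5.78 ± 0.961 to 17.4 ± 1.69 FPKM, and the phosphatidate phosphatase Lpin1 fell from 8.06 ± 3.19 to 1.74 ± 0.678 FPKM. Of 6 lipid droplet proteins and lipases 4 rose and none fell, with Hsd17b13 at 12.5 ± 7.64 and 138 ± 40.3 FPKM and lysosomal lipase (Lipa) at 9.52 ± 4.65 and 24.4 ± 2.14 FPKM. PPAR alpha targets and fatty acid oxidation genes went both ways, with 8 of 21 higher and 8 lower, or 8 and 9 adjusted over the list alone. Fatty acid binding protein Fabp1 rose from 36.2 ± 13.8 to 314 ± 37.4 FPKM while Acot3 and Cyp4a14 fell, and the median of the list lay above 0 while its mean and its test lay below. The camera adjusted p was 0.081 for cholesterol synthesis, where median centring gave 0.031, and 0.25, 0.16 and 0.61 for the other lists in this order. With an estimated correlation the adjusted p for cholesterol synthesis was 0.78, and 0.79 after median centring. Knockout replicate 2 stood apart on the cholesterol list, with a mean log2(FPKM + 1) over its 21 listed genes of 3.70, against 2.68 and 2.55 in knockout replicates 1 and 3 and 1.51 to 2.11 in the libraries labelled wild type. Without knockout replicate 1, 2 or 3 the camera adjusted p of this list with the preset correlation was 0.018, 0.038 and 0.0034. These fits no longer tested genes that reach 1 FPKM only in the libraries labelled knockout. The trend-corrected counts were 4 and 0, 4 and 1, 3 and 1, and 5 and 8.

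In sugar metabolism, 4 of 6 tested glycolysis and glucose uptake genes rose and 1 fell (camera adjusted p = 0.21). The glycolytic kinase Pgk1 rose from 0.256 ± 0.106 to 4.92 ± 0.906 FPKM. In the gluconeogenesis and fasting list 4 of 11 rose and 2 fell (adjusted p = 0.65), with fructose bisphosphatase Fbp1 rising from 1.49 ± 1.12 to 15.9 ± 6.53 FPKM and the transcription factor Foxo1 falling from 12.0 ± 1.80 to 4.49 ± 0.730 FPKM. The trend-corrected counts were 4 and 1, and 2 and 4. Genes of the urea cycle and amino acid catabolism fell in 5 of 12 cases and rose in 3, or 6 and 3 adjusted over the list alone (adjusted p = 0.26, corrected counts 5 lower and 1 higher). The lysine catabolism gene Aass fell from 218 ± 31.0 to 73.6 ± 15.7 FPKM, while methionine adenosyltransferase Mat1a rose from 25.0 ± 4.33 to 184 ± 97.3 FPKM.

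Bile acid synthesis and transport genes rose in 10 of 14 cases and fell in 2 (camera adjusted p = 0.081, 0.022 after the trend correction, with the same counts, and 0.027 after median centring). With an estimated correlation the adjusted p was 0.78, 0.68 after the trend correction and 0.59 after median centring. Without knockout replicate 1, 2 or 3, over the fewer genes then tested, the camera adjusted p with the preset correlation was 0.031, 0.030 and 0.021. The bile salt export pump Abcb11 rose from 0.878 ± 0.702 to 26.2 ± 5.37 FPKM and the oxysterol hydroxylase Cyp7b1 from 18.7 ± 5.35 to 248 ± 26.1 FPKM. Of 21 xenobiotic metabolism genes 12 rose and 5 fell, or 12 and 6 adjusted over the list alone (adjusted p = 0.38, corrected counts 11 and 6). Cyp2c29 rose from 39.7 ± 4.34 to 181 ± 17.1 FPKM, while Cyp2b9 fell from 22.5 ± 12.1 to 0.0859 ± 0.116 FPKM. Antioxidant response genes split into 4 higher and 4 lower of 10 (adjusted p = 0.98, corrected counts 3 and 5), and peroxiredoxin Prdx1 rose from 17.7 ± 4.19 to 339 ± 83.7 FPKM.

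**Figure D3:**
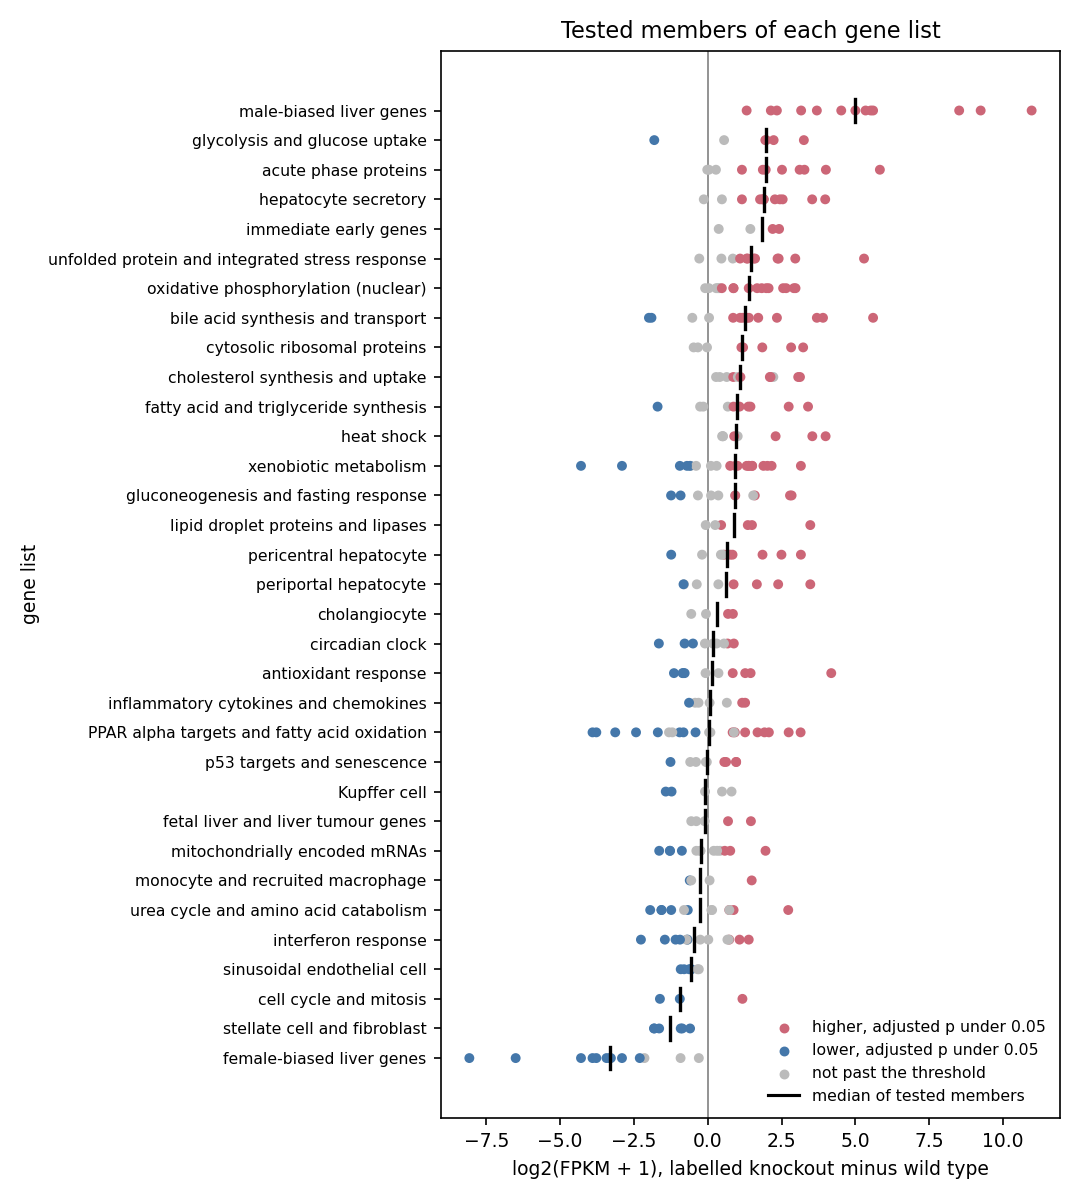
Log2 difference of FPKM + 1, libraries labelled knockout minus libraries labelled wild type, for each tested member (points) of the 33 lists with at least 3 tested members, with the median as a black bar. All 13 tested male-biased genes lie to the right and 10 of 13 female-biased genes are called lower.

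Markers of stromal cells were lower in the libraries labelled knockout. All 6 tested stellate cell and fibroblast markers fell (camera adjusted p = 0.0040), with reelin (Reln) at 7.32 ± 1.69 and 1.63 ± 0.214 FPKM, decorin (Dcn) at 80.8 ± 30.5 and 22.0 ± 6.42 FPKM and lumican (Lum) at 25.0 ± 12.2 and 5.83 ± 1.36 FPKM. Of 7 sinusoidal endothelial markers 5 fell and none rose (adjusted p = 0.024), with the hyaluronan receptor Lyve1 at 4.34 ± 1.04 and 2.04 ± 0.195 FPKM and the cadherin Cdh5 at 2.16 ± 0.840 and 0.637 ± 0.214 FPKM. With an estimated correlation the adjusted p was 0.47 for the stellate and 0.77 for the endothelial list. With the preset correlation the camera adjusted p of the endothelial list rose from 0.024 to 0.082 without wild type replicate 2 and to 0.085 without knockout replicate 3. The trend-corrected counts were 5 and 7 lower. Of the collagen and matrix list 2 genes could be tested, and Lum fell.

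Immune genes moved in both directions. Of 5 Kupffer cell markers 2 fell, Timd4 from 6.98 ± 0.674 to 2.02 ± 0.717 FPKM and Adgre1 from 5.63 ± 0.347 to 1.93 ± 0.874 FPKM, and none rose (camera adjusted p = 0.33, corrected counts 2 lower and 0 higher). Klrd1, a natural killer cell receptor and the only T and NK cell marker tested, fell from 12.8 ± 1.30 to 3.48 ± 0.381 FPKM. Interferon response genes fell in 5 of 14 cases and rose in 3, or 6 and 3 adjusted over the list alone (adjusted p = 0.25, corrected counts 6 lower and 1 higher), with Gbp3 falling from 18.6 ± 9.53 to 2.82 ± 0.724 FPKM and Mx2 rising from 0.575 ± 0.429 to 3.14 ± 1.27 FPKM. Of 7 inflammatory cytokine and chemokine genes 2 rose and 1 fell (adjusted p = 0.97), against 0 and 1 after the trend correction and 1 and 2 after median centring. The inflammatory list had a median and a mean above 0 and a test direction below. Of 4 monocyte and macrophage markers 1 rose and 1 fell (adjusted p = 0.65), Lyz2 from 0.104 ± 0.166 to 2.46 ± 2.18 FPKM and Ccr2 from 2.47 ± 0.632 to 1.26 ± 0.15 FPKM. After the trend correction 0 were higher and 1 lower, where neither of these was called and osteopontin (Spp1) was. Spp1, named here after its values were seen, measured 58.2 ± 8.95 and 40.2 ± 11.8 FPKM and did not pass the test before the correction (adjusted p = 0.094). The mean of this list lay above 0, with median and test below. Ccr2 was also not called without wild type replicate 2 or knockout replicate 3. The single tested neutrophil marker, S100a8, rose from 0.451 ± 0.279 to 1.87 ± 0.503 FPKM, with no call after the correction. The B cell markers Jchain and Ms4a1 measured 20.6 ± 8.04 and 1.94 ± 0.210 FPKM in the libraries labelled wild type and 19 ± 12.5 and 2.32 ± 3.17 FPKM in those labelled knockout, where neither passed the test. Ms4a1 was at 5.98 FPKM in knockout replicate 3, against 0.606 and 0.372 FPKM in knockout replicates 1 and 2.

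Neither list of zonation markers passed the test with all libraries. The pericentral list passed with the preset correlation without knockout replicate 1 or 2, over the fewer genes then tested (camera adjusted p = 0.044 and 0.031). With an estimated correlation in all libraries its adjusted p was 0.78. Of 10 pericentral markers 6 rose and 1 fell (camera adjusted p = 0.18, corrected counts 3 and 1), and of 8 periportal markers 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.65, corrected counts 2 and 2). Pericentral Cyp2e1 rose from 143 ± 77.2 to 1177 ± 177 FPKM and periportal Cyp2f2 from 0.361 ± 0.273 to 6.30 ± 2.66 FPKM. Of 9 circadian clock genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.65), with Nr1d2 falling from 152 ± 25.8 to 50.4 ± 24.7 FPKM and Per3 from 1.26 ± 0.194 to 0.311 ± 0.0544 FPKM. Of 9 p53 targets 4 rose and 1 fell (adjusted p = 0.97), with Mdm2 rising from 3.61 ± 0.841 to 7.88 ± 0.600 FPKM and Perp falling from 181 ± 27.8 to 74.6 ± 4.74 FPKM. The trend-corrected counts were 1 higher and 3 lower for the clock and 2 and 1 for p53 targets. The clock list had a median above 0 with a mean and test below, and the p53 list a median below 0 with a mean and test direction above. Of 3 cell cycle genes tested, Pcna rose from 3.84 ± 1.00 to 9.78 ± 0.794 FPKM, and the cyclins Ccnd1 and Ccne2 fell from 10.6 ± 6.75 to 2.45 ± 0.897 FPKM and from 5.89 ± 1.30 to 2.55 ± 0.413 FPKM (adjusted p = 0.55), the last without a call after the correction. Of 5 fetal liver and tumour genes 2 rose (adjusted p = 0.97), with Cd24a at 2.45 ± 0.668 and 9.29 ± 5.27 FPKM, while 1 was higher and 3 lower after the correction and 1 and 2 after median centring, and the mean of this list lay above 0 with median and test below. Of 4 immediate early genes 2 rose (adjusted p = 0.26, none called after the correction), with Dusp1 at 1.53 ± 0.542 and 15 ± 11.3 FPKM. The camera adjusted p of this list was 0.012 without knockout replicate 2, over the fewer genes then tested, and 0.78 with an estimated correlation in all libraries.

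Markers of other tissues were mostly too low to test. Of 4 cholangiocyte markers 2 rose, among them Sox9 from 0.752 ± 0.327 to 1.81 ± 0.511 FPKM (camera adjusted p = 0.81). The counts turned to 0 higher and 1 lower after the trend correction, where Spp1, which is also on this list, was the lower one, and to 1 and 1 after median centring. Sox9 was also not called after median centring, without wild type replicate 3 or without knockout replicate 3. On the adipocyte list, Fabp4 measured 0.684 ± 0.416 FPKM in the libraries labelled wild type and 3.16 ± 2.70 FPKM in those labelled knockout. Car3 measured 592 ± 236 and 977 ± 517 FPKM, and the limma adjusted p was 0.17 and 0.21. Car3 at 592 FPKM beside Fabp4 at 0.684 FPKM need not come from adipocytes. The only tested gene of the pancreas and gut list, intestinal fatty acid binding protein Fabp2, rose from 3.91 ± 2.25 to 36.5 ± 16.4 FPKM. No member of the erythroid, muscle or mesothelial lists reached the filter, so 0 of each list were tested.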

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

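Genes higher in the libraries labelled knockout numbered 3171 without a filter (20529 genes tested), 468 at 10 FPKM or more (1746 tested), 1102 with an absolute log2 change of at least 1, and 966 to 1957 when each library was left out. Genes lower numbered 559 at 10 FPKM or more, 415 with an absolute log2 change of at least 1, 1891 after median centring, 1761 after quantile normalization, and 727 to 1039 with each library left out. The filter and fewer libraries change how many genes are tested, and the cause was not tested for the scalings. The log2 difference of Cdkl3 was -0.10 after median centring, -0.14 after quantile normalization, -0.023 after the GC correction and -0.020 after the GC and length correction. It ran from -0.017 to 0.059 with each library left out, with no call in any of these fits. Rescaling moves values near 0 such as these, so the shifts do not by themselves show a change of Cdkl3. Its reads numbered 68 in the libraries labelled wild type and 69 in those labelled knockout. Lists past the threshold numbered 16 without a filter, 0 with an estimated correlation, 21 with fry, which does not compare a list with other genes, and 7 to 12 with each library left out. The log2 difference of Abhd5 changed sign after quantile normalization, to -0.034. Of 141 named genes 107 gave the same call in each setting that tested them, and the settings that lost the most calls were the GC and length correction (21 genes) and the GC correction (16 genes). With the replicate number as a block 1740 genes were higher and 1031 lower. Deviations of same-numbered libraries correlated at -0.049, -0.096 and 0.18, and those of differently numbered libraries from -0.35 to 0.35. The numbers thus show no pairing, and 3 such values cannot exclude it. The count-based alternatives (count tests and their normalizations) do not apply to FPKM values. With 3 libraries per group, no permutation test of a single gene can go below 0.1.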

Other observations

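The tests of genes that escape X inactivation and of kidney markers not looked at before were set before their values were seen, and the other tests were chosen after the results were seen. Albumin (Alb) measured 324 ± 88.4 FPKM in the libraries labelled wild type and 1137 ± 441 FPKM in those labelled knockout. Some other transcripts that are abundant in liver were listed near 0 in each library. Apoe reached at most 0.213 FPKM, Gapdh 0.237 FPKM and Rplp0 0.429 FPKM, and their transcripts have 59.5%, 52.6% and 52.9% GC. Apoa1 (56.8% GC) reached 1.94 FPKM in knockout replicate 2, and Actb (51.1% GC) reached 20.8 FPKM in knockout replicate 3. The muscle genes Neb and Ttn varied between libraries of the same group, with Neb at 10.4 FPKM in knockout replicate 3, 6.41 and 3.84 FPKM in wild type replicates 2 and 3 and 0.571 to 1.07 FPKM in the other 3 libraries. In wild type replicates 2 and 3 the muscle gene Myh4 was at 0.0034 FPKM and a listed 0, and Acta1 and Ckm were listed at 0. The mean log2(FPKM + 1) of the fixed muscle list was 0.598 in knockout replicate 3 and 0.142 or less in each other library. These genes were chosen after their values were seen.

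Xist and the Y-linked genes parted the groups in 6 of 6 libraries, and the means of the sex-biased lists went with them. The mean log2(FPKM + 1) of the male-biased list was 1.53 to 2.06 in the libraries labelled wild type and 5.63 to 5.95 in those labelled knockout. For the female-biased list it was 3.505 to 3.94 and 1.155 to 1.33. A change of hormone state in mice that are all male is argued against by Xist, whose lowest value in the libraries labelled wild type was 7034 times its highest in those labelled knockout. The label that calls all mice male is argued against for the libraries labelled wild type. There Xist ran from 192 to 292 FPKM and the 4 Y-linked genes reached at most 0.881 FPKM, in Eif2s3y. Origin of the libraries labelled wild type from females and of those labelled knockout from males goes with these values. How the label came to differ was not tested. Of the genes that escape X inactivation, Kdm5c and Ddx3x were lower in the libraries labelled knockout and Kdm6a and Eif2s3x were not called. Their median log2 difference after the trend correction lay at -0.385 relative to 250 other X-linked genes, at percentile 12.59 of 10000 random sets, which with 4 genes leaves that test open. An effect of Cdkl3 genotype cannot be told apart from sex, since 0 libraries had the sex opposite to the rest of their group.

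Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 3068 genes, and the highest other gave 10. With 10 splits the share cannot fall under 0.05.

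The lists of secretory, acute phase, oxidative phosphorylation and stress response genes were higher in the libraries labelled knockout. Recovery that depends on GC content and length may account for part of this, since high-GC transcripts were lower in the libraries labelled wild type and the list medians fell when that trend was removed, as from 1.96 to 1.19 for the acute phase list. After the removal 4 of these 4 lists stayed past the threshold with the preset correlation. None passed with an estimated correlation, either before (camera adjusted p = 0.78) or after the removal (camera adjusted p = 0.68). The lists were chosen because they had passed, and the removal takes out only a smooth trend on GC content and length. What is left can still hold differences of recovery, so the test does not decide whether recovery is the whole cause. A higher share of hepatocytes would go with the lower stellate cell (6 of 6) and sinusoidal endothelial (5 of 7) markers and may add to the pattern. Of 12 urea cycle and amino acid catabolism genes 5 fell and 3 rose, and that list did not pass its test (camera adjusted p = 0.26). Of all 5673 tested genes 1157 were lower, and single hepatocyte genes can fall while the share rises. These falls therefore do not decide whether a higher share is the whole cause of the higher lists. Sex of the animals and genotype stay open as well.

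Kidney transcripts stood out in knockout replicate 1. Of 13 kidney markers not looked at before, all detected somewhere, 11 had their highest value in this library, where 2.17 would by equal chance. Of the 19 of 27 listed markers that could be matched, 9 besides Kap were at 1 FPKM or more there and at least 10 times as high as in any other library, which argues against a rise of Kap alone. Among these 9, Slc7a13 measured 35.3 FPKM, Acsm2 21.7 FPKM and Slc22a6 3.13 FPKM. Slc12a1, not among them, measured 9.77 FPKM, or 7.2 times its highest value in another library. Umod, abundant in kidney, measured 0.251 FPKM and Napsa was listed at 0. In another library 3 of the 19 markers, Kap, Slc12a1 and Atp6v0d2, reached 1 FPKM. Kidney tissue in that sample is a candidate source, and no biological explanation other than a rise of Kap was tested.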
